A study of Drosophila melanogaster with 9 samples.

How the data were processed

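Polyadenylated RNA of Drosophila melanogaster first instar larvae was sequenced in 9 libraries, 3 from wild-type males, 3 from males lacking both roX RNAs (roX1[ex6] roX2[9-4], called roX-KO males below) and 3 from wild-type females. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase I and selected on oligo dT beads, and after second-strand synthesis and adaptor ligation it was read as 100 base paired ends on a DNBSEQ instrument. The protocols mention no step that marks the strand.

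The authors deposited 1 file of raw read counts per library, with 1 count for each of 17611 gene IDs and closing lines for reads that were not assigned to a gene. Per the submitters' processing notes, HISAT2 2.2.1, SAMtools 1.13, HTSeq 2.0.2 and DESeq2 were used with the dm6 genome; the notes give these programs no role or setting, and the strand setting of the counting and the annotation release are not given in the sources used here. The authors also deposited a table for the 6 male libraries with FPKM values, a mean signal per gene over libraries, log2 fold changes with standard errors on the log2 scale, a test score, p-values and adjusted p-values, per the file headers. The deposited FPKM were checked to be the counts multiplied by 1 factor per gene and 1 per library that followed DESeq2's size factors. Gene symbols, positions, strands and exon lengths came from a dm6 annotation, which matched 17556 of the IDs and left 55 unmatched. The table of the male libraries was set beside the recomputed calls, and its FPKM were used only as an alternative.

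The counts summed to between 17318293 and 18020359 per library. Each comparison was fitted on its 6 libraries alone. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, scaled by TMM and tested with edgeR's quasi-likelihood F-test with robust dispersions (edgeR 4.0.16, limma 3.58.1, R 4.3.3). The p-values were adjusted by Benjamini and Hochberg over the genes tested, and genes under 0.05 were called higher or lower. Log2 CPM used a prior count of 2. A fold against a group with 0 counts is a lower bound computed against a floor of 3 counts over the group; with 1 to 3 counts, the ratio is given with its 95% counting interval. Intervals and floors cover counting error only. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.

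Shifts of the X, of chromosome 4 and of pericentromeric genes were measured in each library as the median deviation of log2 CPM over those genes minus the median over the genes of arms 2L, 2R, 3L and 3R, and groups were compared with an exact two-sided permutation test, whose smallest possible p for 3 libraries against 3 is 0.1. Pericentromeric genes lie on 2L from 22.2 Mb, 2R up to 5.7 Mb, 3L from 23 Mb and 3R up to 4.2 Mb; they were compared with the other genes of those arms. Calls on the X and on the arms were compared with Fisher's exact test over genes, which are not independent.

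The 31 gene lists were the MSL complex and roX RNAs, dosage compensation cofactors, sex determination, Hox genes, Polycomb target developmental regulators, the Polycomb group, the trithorax group, heterochromatin factors, Y-linked genes, heat shock, detoxification and oxidative stress, antimicrobial and immune, apoptosis with p53 and DNA damage, the ecdysone pathway, cuticle proteins, digestive enzymes, larval serum and fat body, glycolysis and sugar metabolism, cytosolic ribosomal proteins, oxidative phosphorylation, DNA replication and cell cycle, neurons, neural stem cells, glia, body wall muscle, hemocytes, trachea and epidermis, Malpighian tubules and hindgut, germline, testis-specific transcription, and yolk and female reproductive genes. Of their symbols, 9 had no match and were dropped. Some genes belong to more than 1 list. Lists with more than 1 tested gene, which leaves out the Y-linked list, were tested with camera at a preset correlation of 0.01. An estimated correlation and fry were set beside it. The p-values were adjusted over the lists of a comparison. The X, chromosome 4 and pericentromeric sets were tested alike, but adjusted only among themselves. Camera compares a list with the other genes, and fry asks whether its genes move on balance in 1 direction. With an estimated correlation camera refers its test to the number of libraries and not of genes, which by itself raises p-values. Between the male groups the unadjusted camera p of heat shock went from 9.41e-18 to 0.000934 with an estimate of 0.00666. That of the X went from 1.82e-08 to 0.00154 with 0.00505. An estimated correlation can thus end a call even where the estimate is under 0.01, so a lost call need not come from correlated genes. Genes were named by a rule: roX1 and roX2 always; among genes past the threshold with mean log2 CPM of at least 1 and no overlap between groups, the 6 largest rises and 6 largest falls, and the same for symbols that are not bare CG or CR numbers, with 4 each way on the arms and on the X in the comparison of males; up to 4 members of each list; and all members of the MSL, Hox and sex determination lists. The lists, the rule, the tests and most alternatives were set before the data were examined.

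The steps were tested on simulated counts with 200 changed genes. For roX-KO against wild-type males, 11073 simulated genes gave recovery of 98.5% of changes of 1.5-fold, 100% of 2-fold and 100% of 4-fold, with 15 false calls. For wild-type females against males, 11024 genes gave 11.9%, 38.8% and 97.0%, with 8 false calls. For roX-KO males against wild-type females, 11089 genes gave 5.97%, 65.7% and 100%, with 4 false calls. A simulated X shift of -0.5 was recovered as -0.498, -0.482 and -0.503, and a list shifted by 1 was called with 0 of the 29 other lists. Simulated genes were drawn independently, so this says nothing about false calls of lists whose genes are correlated. In the data the shifted list, oxidative phosphorylation, had an estimated correlation of 0.594 for roX-KO against wild-type males.

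Alternatives were DESeq2 1.42.0, limma-voom, DESeq2's size factors, TMM factors from the arms alone, total counts, no low-count filter, a minimum of 50 counts in 3 libraries, all 9 libraries in 1 fit, the replicate number as a block, a 1.5-fold threshold with glmTreat, an adjusted p of 0.01, the deposited FPKM, other summaries and priors for the shifts, and leaving out each library in turn.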

Results

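RNA from whole first instar larvae was counted over genes in 3 groups of 3 libraries each: wild-type males, males that lack the noncoding RNAs roX1 and roX2, and wild-type females. In male flies the MSL complex, of which the roX RNAs are part, binds the single X and raises its transcription. The series asks what the roX RNAs do in transcription, and its title points to repression of autosomal genes. Counts in genes came to 17836294, 17845312 and 17743217 in the wild-type males, 17724794, 17318293 and 17942186 in the roX-KO males, and 17904523, 17979810 and 18020359 in the females. The labels do not say that replicates came from separate cultures or animals, so p-values measure only the spread between these libraries. Replicates of each male group correlated at Pearson's r of 0.991 to 0.996 over genes. Female libraries 1 and 2 correlated at 0.996, while female 3 correlated with them at 0.955 and 0.958.

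The roX counts matched the group labels in all 9 libraries, although the protocol text of the female samples, like that of the others, names males. For roX1 (FBgn0019661, X, 3857230 to 3862697, dm6) there were 5571, 4964 and 6002 counts in the wild-type males, 63, 52 and 68 in the roX-KO males, and 440, 403 and 314 in the females. For roX2 (FBgn0019660, X, 11579065 to 11580432) there were 150, 181 and 162 counts in the wild-type males, 0, 0 and 0 in the roX-KO males, and 3, 4 and 6 in the females. In roX-KO males roX1 had a log2 fold of -6.72 ± 0.12 (SE, n = 3 per group) against wild-type males (edgeR adjusted p = 2.49e-12), and roX2 was at least 191-fold lower. In females roX1 had a log2 fold of -3.88 and roX2 of -5.24 against wild-type males.

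**Figure D1:**
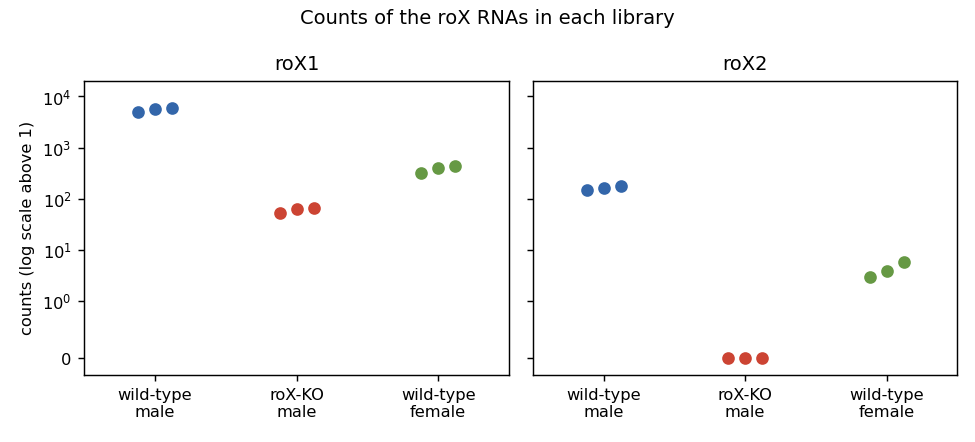
Read counts of roX1 and roX2 in each of the 9 libraries, on a scale that is logarithmic above 1. Points are libraries, grouped as wild-type male, roX-KO male and wild-type female; roX2 has 0 counts in the roX-KO males.

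In roX-KO males the X chromosome lost expression as a whole, a set call that held with an estimated correlation between genes (adjusted p = 0.00461). Chromosome 4 genes and genes next to the centromeres were more often higher than lower, but as sets they lost their calls with an estimated correlation (0.504 and 0.361). The heat shock list was also lower and held its call (0.028), and it was lower in females against wild-type males as well. Most cuticle, muscle, tracheal and oxidative phosphorylation genes were lower and most neuronal and Polycomb group genes higher. These lists lost their calls with an estimated correlation (0.0919 to 0.641). For muscle the estimate was -0.0286, under the preset 0.01, so correlated genes do not explain that loss. By fry, which does not compare a list with the other genes, these lists were all called in the same direction. The fry adjusted p ranged from 4.01e-06 for muscle to 0.00579 for oxidative phosphorylation. Of 11172 genes tested against wild-type males, 3505 were higher and 3588 lower (63.5% changed), 580 of them higher and 979 lower by at least 2-fold. The groups did not overlap in 7759 genes (69.5%), where chance gives 10%. In the deposited table of these libraries 3107 genes were higher and 3443 lower, and 6404 genes were called the same way in both.

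On the X, 1031 of 1751 tested genes fell (58.9%) and 233 rose (13.3%), with a median log2 fold of -0.41. On arms 2L, 2R, 3L and 3R, 3212 of 9286 genes rose (34.6%) and 2523 fell (27.2%), with a median of 0.08. X genes were less often higher (odds ratio 0.29, Fisher's exact p = 1.08e-78) and more often lower (odds ratio 3.84, p = 3.95e-140) than arm genes. Of all genes called higher, 91.6% lay on the arms (95% interval 90.7 to 92.5%), which hold 83.1% of the genes tested. The interval treats genes as independent, which they are not, and the low share of X genes called higher raises this value by itself. Relative to the arms within each library, the X was at -0.24 ± 0.02 (SD, n = 3) in roX-KO males and 0.24 ± 0.01 in wild-type males, a difference of -0.47, so that X expression fell by 28% (exact permutation p = 0.1, the smallest possible). Chromosome 4 genes shifted by 0.24 (exact permutation p = 0.1), with 51 of 92 higher and 15 lower, and pericentromeric genes by 0.30 (permutation p = 0.1), with 80 of 135 higher and 13 lower. Without wild-type male 2 the chromosome 4 shift was 0.15. Of 18 mitochondrial genes, 15 fell and 0 rose, with a median of -1.04; mt:lrRNA, the large ribosomal RNA of the mitochondrion, had a log2 fold of -1.15. Mitochondrial genes took 7.13% ± 1.14 (SD, n = 3) of counts in roX-KO males and 10.7% ± 1.43 in wild-type males. In females they took 6.77% ± 1.19, so the share was highest in wild-type males. Against females 1 of 17 mitochondrial genes was lower in roX-KO males and 0 higher, with a median of -0.423.

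The balance of higher and lower genes depended on scaling. With factors from the arms alone 3052 genes were higher and 3966 lower, and the share of changed arm genes that were higher went from 56.0% to 49.6%. With total counts, which moved the median of all genes by 0.23, 5467 were higher and 2395 lower, and 69.5% of calls were higher in place of 49.4%. The X shift is a difference within libraries and carries no such factor.

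**Figure D2:**
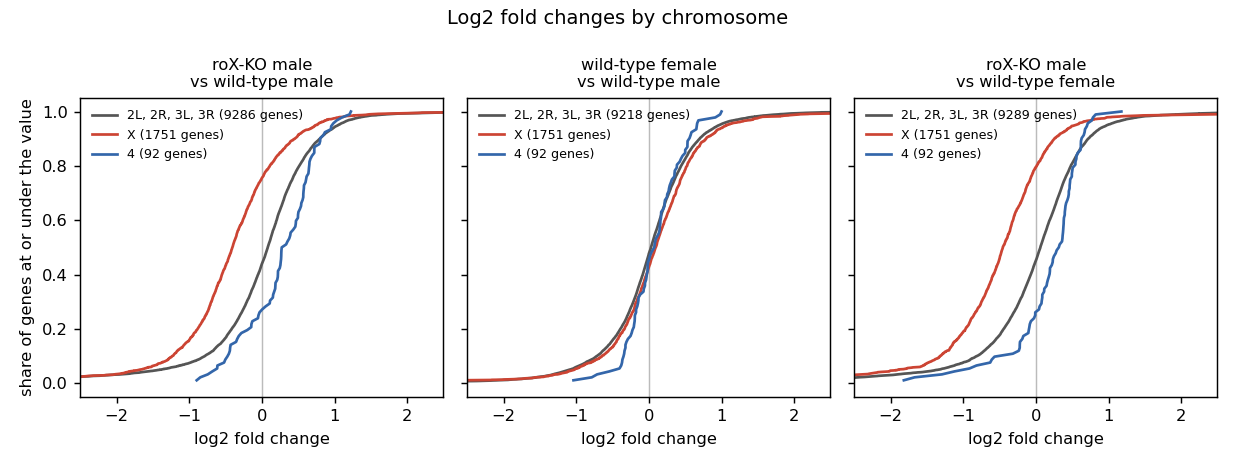
Cumulative share of genes (vertical axis) at or under each log2 fold change (horizontal axis) for the arms 2L, 2R, 3L and 3R, the X and chromosome 4, with 1 panel per comparison. In both comparisons of roX-KO males the curve of the X lies to the left of that of the arms, with medians of -0.41 against wild-type males and -0.45 against females.

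**Figure D3:**
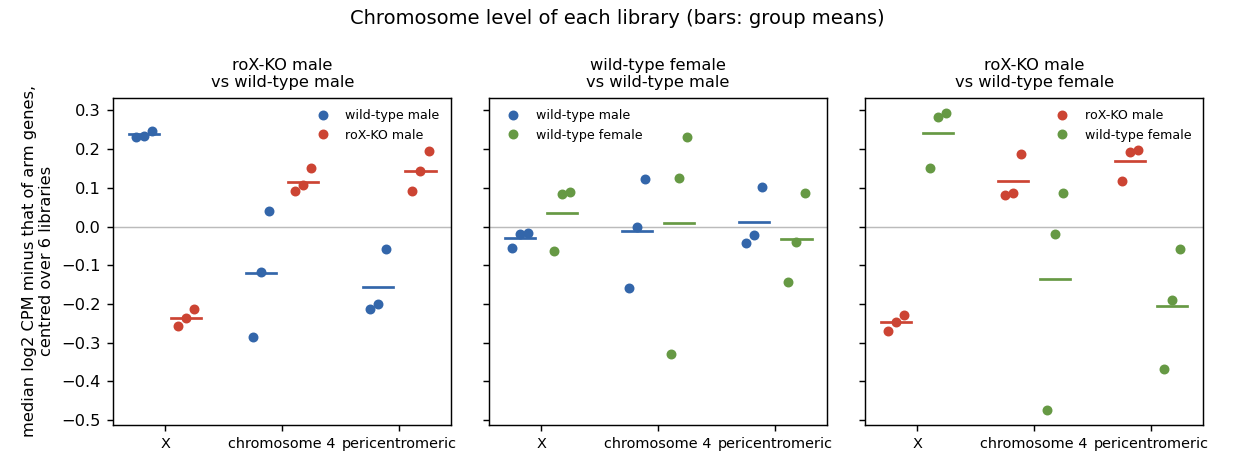
Median log2 CPM deviation of X, chromosome 4 and pericentromeric genes minus that of arm genes, centred over the 6 libraries of each comparison. Points are libraries and bars are group means; on the X the roX-KO males lie below both wild-type groups, with differences of -0.47 and -0.49.

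Among the strongest rises in roX-KO males were CG9360 on the X, a predicted short-chain dehydrogenase (log2 fold 5.75 ± 0.07 SE), the X gene CG32751 (4.75), Bace, a midgut aspartic protease (4.61 ± 0.27), the stress-induced humoral factors TotC (4.21) and TotA (3.48), the predicted serine protease CG17571 (3.66), the cytochrome P450 Cyp4e3 (3.51), the oxidoreductase gene fiz (3.45) and rib, a transcription factor of tracheal and salivary gland morphogenesis (3.16). X genes that rose also included the nuclear receptor Hr4 (1.27) and tay (1.16), which acts in locomotor behaviour. Lgr4 also rose (adjusted p = 0.00103), but 29.2% of its exon length lies under a gene on the other strand, so its value is uncertain. The deepest falls were in Acbp3, an acyl-CoA binding protein gene (2240-fold lower, 95% counting interval 620 to 18500), CG15599 on the X (at least 197-fold lower), CG14147 (-9.39), the cuticle protein genes Cpr65Ea (-8.63) and Twdlbeta (-7.62), nol (-8.60) and sordd2 on the X (-7.33). The X gene v, which encodes tryptophan dioxygenase of the eye pigment pathway, was at -4.62; the labels do not give the stocks, so a marker difference between them cannot be told apart from the knockout for such a gene.

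The genes of the MSL proteins did not move together. Of the 7 members of the MSL list 3 rose (mle 0.72, msl-2 0.44, msl-3 0.41) and 3 fell (roX1, roX2 and the acetyltransferase gene mof, -0.68, all on the X). The value of mof lay between the quartiles of all tested X genes (-0.771 and -0.00785), so it is not set apart from the fall of the X. The gene msl-1 was at 0.23 with an adjusted p of 0.0521, and it passed adjusted over the list alone. The list median was positive (0.23) while its mean and camera test were negative (adjusted p = 0.0228, 0.414 with an estimated correlation), which rests on roX1 and roX2. The dosage compensation cofactors had 5 of 12 higher and 1 lower, and 9 and 0 with total counts (adjusted p = 0.363), among them Su(var)3-7 (0.47) and Clamp (0.41). The sex determination list had 5 of 12 higher and 2 lower (adjusted p = 0.428): Ythdc1, a reader of RNA methylation, rose by 1.00 and tra by 0.66. The X gene snf was at -0.73 and fru at -0.65, and Sxl, also on the X, did not pass (-0.03). These 2 lists had the same counts adjusted over the list alone.

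Of the chromatin lists, the Polycomb group, its targets and the trithorax group passed with the preset correlation and not with an estimated one. In the Polycomb group 18 of 21 genes were higher and 0 lower, the same adjusted over the list alone, with a median of 0.45 (camera adjusted p = 0.00904, 0.641 with an estimated correlation); jing rose by 0.80, Kdm2 by 0.70 and pho by 0.35. Of 65 Polycomb target developmental regulators 39 rose and 4 fell (40 and 4 adjusted over the list alone, 49 and 2 with total counts; adjusted p = 0.00904, 0.641 estimated), with tio at 1.04 and the X genes ase and gt at -1.08 and -1.14. The trithorax group had 12 of 17 higher and 1 lower (the same over the list alone; adjusted p = 0.0273, 0.641 estimated); the cohesin gene vtd rose by 0.84 and the demethylase gene Utx by 0.83, and Trl was at -0.63. Of 8 Hox genes 5 rose and 0 fell, also over the list alone (pb 0.78, Scr 0.57, lab 0.53, abd-A 0.49, Abd-B 0.43), with adjusted p = 0.26 for the list; Dfd, Ubx and Antp did not pass. Heterochromatin factors had 6 of 16 higher and 2 lower (the same over the list alone, 10 and 1 with total counts; adjusted p = 0.424), with ADD1 at 0.71 and vig2 at -0.45.

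Lists of the outer body layers, muscle, energy supply and digestion differed in their calls. Cuticle proteins had 95 of 109 genes lower and 8 higher (96 and 9 adjusted over the list alone) with a median of -2.62 (camera adjusted p = 1.08e-70, 0.147 with an estimated correlation); Cpr47Ed (2.18) and Cpr49Ac (1.59) went the other way. Of 16 trachea and epidermis genes 12 fell and 0 rose (13 and 0 over the list alone; adjusted p = 5.48e-06, 0.258 estimated), including the chitin-binding obst-A (-3.07) and the chitin deacetylase serp (-1.72). Body wall muscle had 19 of 20 lower and 0 higher (the same over the list alone; adjusted p = 9.35e-06, 0.0919 estimated), with the troponin I gene wupA on the X at -1.32 and TpnC73F at -1.22. Oxidative phosphorylation had 57 of 62 lower and 1 higher (the same over the list alone; adjusted p = 1.91e-05, 0.641 estimated), with ND-B14.5A at -1.29. Glycolysis and sugar metabolism had 13 of 22 lower and 1 higher (the same over the list alone; adjusted p = 0.142), and 4 of each with total counts, with the X gene Gapdh2 at -0.90 and fbp at -0.89. Larval serum and fat body genes had 11 of 23 lower and 6 higher (12 and 7 over the list alone, 11 and 10 with total counts; adjusted p = 0.485). The X gene Lsp1alpha was at -3.22 and the insulin target tobi rose by 1.05. Digestive enzymes had 30 of 55 lower and 15 higher (the same over the list alone; 22 and 18 with total counts; adjusted p = 0.0252, 0.641 estimated): the lysosomal mannosidase genes LManIII (-5.56) and LManIV (100-fold lower, interval 33.9 to 489) fell and the protease Jon66Cii rose (1.74).

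Heat shock genes were lower in 12 of 14 cases and higher in 0, the same over the list alone, with a median of -2.08; camera called the list with the preset (adjusted p = 1.41e-16) and the estimated correlation (0.028). Hsp70Aa had -5.07, Hsp70Ba -4.44, and the co-chaperone stv -0.90; reads of the Hsp70 copies cannot be told apart with certainty. Detoxification genes had 24 of 42 lower and 8 higher (the same over the list alone; adjusted p = 0.0294, 0.641 estimated), and 18 lower and 14 higher with total counts, which ended the call (0.0677), with Cyp6a17 at -6.38 and Cyp6a2 at -3.70. Immune genes had 14 of 32 lower and 8 higher (the same over the list alone, 13 and 12 with total counts, 14 and 5 with arm factors; adjusted p = 0.265), with CecA1 at -2.01 and PGRP-SB1 at -2.23 beside the raised Tot genes. The apoptosis, p53 and DNA damage list had 15 of 25 higher and 2 lower (16 and 2 over the list alone; adjusted p = 0.0294, 0.301 estimated, and 0.0507 without wild-type male 2): mre11 rose by 1.84 and hid by 1.27, while Gadd45 was at -1.12. In the ecdysone pathway 12 of 27 rose and 6 fell (the same over the list alone, 19 and 4 with total counts; adjusted p = 0.29), with Hr3 at 1.74, Ptth at 1.34, Eip74EF at -1.67 and ftz-f1 at -1.66.

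Of the nervous system lists, neurons passed with the preset correlation alone, and glia and neural stem cells did not pass. Neurons had 17 of 19 genes higher and 1 lower (the same over the list alone) with a median of 0.84 (camera adjusted p = 3.94e-05, 0.641 with an estimated correlation); onecut rose by 1.23 and the presynaptic Rim by 1.17, and the X gene elav was at -0.53. Glia had 6 of 10 higher and 2 lower (adjusted p = 0.142), among them the astrocyte gene alrm and, at 0.72, the glial fate gene repo. Neural stem cells had 4 of 7 lower and 1 higher, and 4 and 3 with total counts (adjusted p = 0.716), with wor at -1.26 and pros at 0.61. Hemocytes had 6 of 13 lower and 2 higher (8 and 2 over the list alone, 3 and 3 with total counts; adjusted p = 0.0973, and 0.0427 without wild-type male 2), with the prophenoloxidases PPO1 and PPO2 of crystal cells at -1.93 and -1.88. DNA replication and cell cycle had 14 of 37 lower and 5 higher (13 and 5 over the list alone, 5 and 14 with total counts; adjusted p = 0.826), with the X gene Mcm3 at -0.85 and CycB3 at 0.64. Ribosomal proteins had 22 of 88 lower and 3 higher (20 and 2 over the list alone, 9 and 39 with total counts; adjusted p = 0.84), with RpL37-2 at -1.81 and RpL15 at 0.74. The glia and neural stem cell counts were the same over the list alone.

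Reproductive and excretory lists did not pass as sets. Malpighian tubules and hindgut had 6 of 15 higher and 3 lower, and 5 of each with arm factors (adjusted p = 0.397), with urate oxidase Uro at 2.24. Germline genes had 5 of 18 higher and 5 lower, and 6 and 0 with total counts (adjusted p = 0.773), with piwi at 0.51. Testis-specific transcription had 1 of 6 higher, topi (1.28), and 1 lower, vis (-1.28), with adjusted p = 0.954. Of 2 yolk and female reproductive genes fs(1)N rose (3.10) and Yp3 was at -0.80 (adjusted p = 0.485). These 4 lists had the same counts over the list alone, and the germline and testis lists had a median and a test of different sign. Of the Y-linked list only FDY was tested and rose (1.71). The direction of the Malpighian list flipped with factors from the arms, and those of the ribosomal, DNA replication, germline and testis lists with total counts. Total counts move all genes up alike (by 0.231), so a median near 0 changes sign by that alone, and these flips tell nothing about the lists; for testis only the direction of the test changed, far from passing (0.869). In this comparison 13 lists passed camera; of these, heat shock alone held with an estimated correlation. With the preset correlation, chromosome 4 genes had 0.00251 and pericentromeric genes 1.97e-05.

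**Figure D4:**
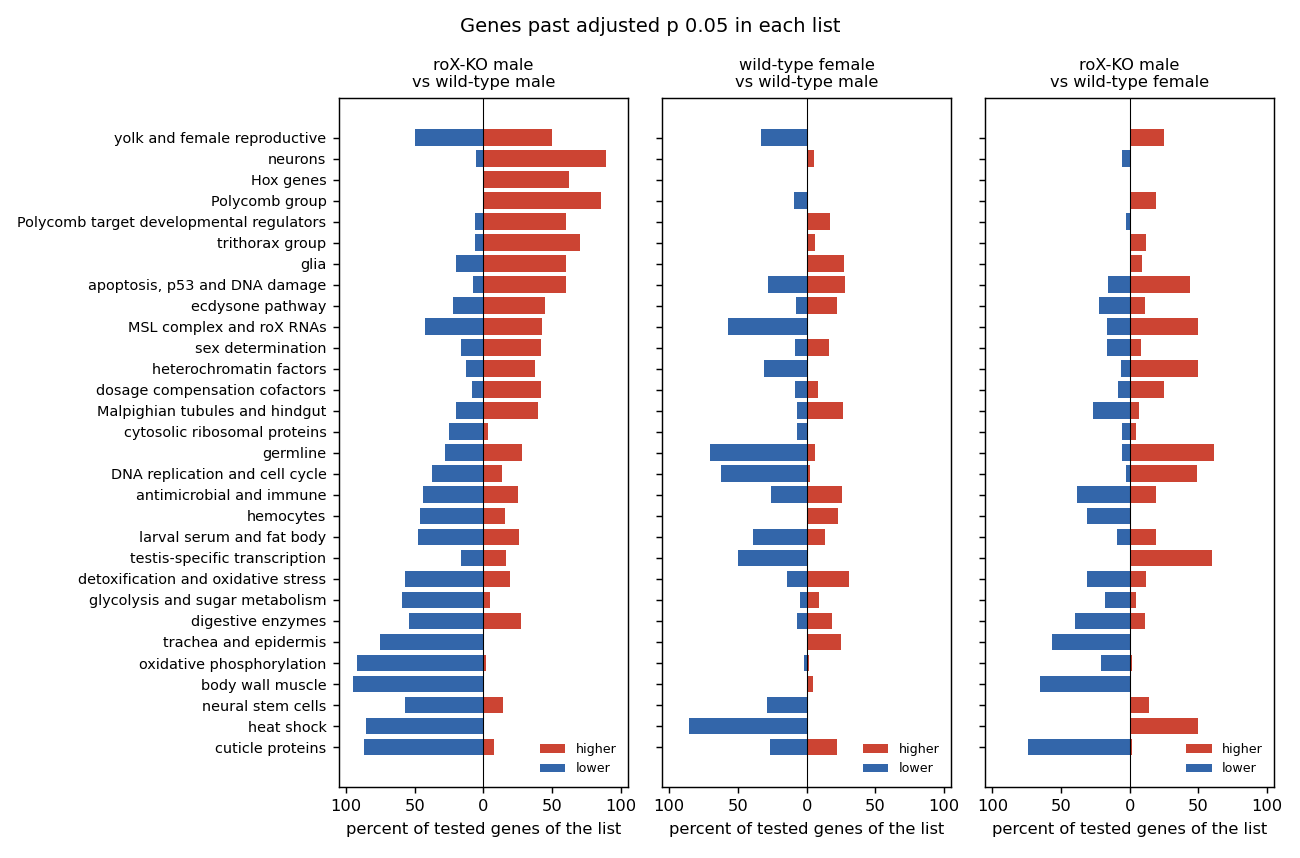
Percent of the tested genes of each list that were higher (right) or lower (left) at an adjusted p under 0.05, with 1 panel per comparison and lists ordered by their median log2 fold in roX-KO against wild-type males. Cuticle proteins had 95 of 109 genes lower against wild-type males and 79 of 107 lower against females.

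Females, which do not assemble the MSL complex, differed from males in germline and cell cycle genes, in heat shock genes and in X genes that include a block near w, while the shift of the X as a whole against the arms was small and differed between the female libraries. The comparison sets the changes in roX-KO males beside the difference between the wild-type female and male libraries. Of 11104 genes 1197 were higher in females and 1244 lower (22.0% changed), 480 and 605 of them by at least 2-fold, and groups did not overlap in 4632 genes (41.7%, where chance gives 10%). The biological coefficient of variation was 0.198, against 0.0763 between the male groups. The female libraries were submitted after the others, and a batch cannot be told apart from sex. The labels do not say whether the wild-type males and females come from the same stock. Leaving out female 3 gave 2927 higher and 2924 lower genes. Leaving out wild-type male 1, 2 or 3 gave 452, 562 or 430 higher and 616, 694 or 638 lower. Leaving out female 1 or 2 gave 770 or 686 higher, and 763 were lower without female 2.

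The X shift between females and males was 0.07 (exact permutation p = 0.4), that of chromosome 4 was 0.02 (p = 0.9) and that of pericentromeric genes -0.04 (p = 0.6). On the X, females 1 and 2 (0.0885 and 0.0827) lay above every male library (at most -0.0156), and female 3 (-0.0642) lay below them all; the spread within groups, 0.063, comes largely from female 3, and without it the shift was 0.10. Leaving out 1 library moved the X value between 0.04 and 0.10 and that of chromosome 4 between -0.11 and 0.19. On the X 228 of 1751 genes were higher and 180 lower, and on the arms 963 of 9218 were higher and 1050 lower. X genes were slightly more often higher (odds ratio 1.28, Fisher's exact p = 0.00191) and not measurably less often lower (0.891, p = 0.186). Of 18 mitochondrial genes 6 were lower and 0 higher.

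The largest folds above the male libraries lay in X genes, where a difference of stock cannot be told apart from sex: CG14418 (log2 fold 10.01), CG3588 (7.42), CG14417 (6.47), CG14419 (6.02), the eye pigment transporter gene w (5.42) and CG1304 (5.08). Also higher were Cpr47Ed (2.85), Ser6 (2.59), spz6 (2.37) and the aminotransferase gene Agxt (2.85), which lies on the X and has the same limit of stock. PGRP-SC1b (2.33) has a near-identical copy and is uncertain. Lower in females were genes with germline expression, among them the ribosomal protein genes RpL22-like (-7.05) and RpS19b (-5.20), gNacalpha (-5.32) and blanks (-4.68). CG12477 was at least 83.3-fold and CG42857 at least 77.5-fold lower, CG3251 219-fold lower (counting interval 38.9 to 8690), CG15930 124-fold lower (42.1 to 604) and CG15599 at -6.15. The Y-linked FDY was at -4.61.

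The germline list had 12 of 17 genes lower and 1 higher, also over the list alone (camera adjusted p = 3.35e-07, 0.04 with an estimated correlation): vas was at -3.32, aub at -3.03 and piwi at -1.26. DNA replication and cell cycle genes had 23 of 37 lower and 1 higher (27 and 1 over the list alone; adjusted p = 2.12e-09, 0.0256 estimated), with CycB at -1.67 and polo at -1.68. Heat shock genes had 12 of 14 lower and 0 higher, also over the list alone (adjusted p = 1.22e-23, 0.0115 estimated). Of the 7 lists called, these 3 held with an estimated correlation. By fry the Polycomb targets alone lost their call (adjusted p = 0.229). The MSL list had 4 of 7 lower and 0 higher (5 and 0 over the list alone; adjusted p = 7.48e-05, 0.193 estimated). In it msl-2, whose translation is blocked in females, was at -1.83 with an adjusted p of 0.0171, and 0.0656, 0.0511 and 0.0648 without wild-type male 1, 2 and 3; mof was at -0.95 (0.0222; 0.0639 without wild-type male 1 and 0.0614 without female 2). msl-1, msl-3 and mle did not pass. Of the sex determination list 2 of 12 were higher and 1 lower (adjusted p = 0.751), with Sxl, the female switch gene, at 1.05 (0.00932).

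Larval serum and fat body genes had 9 of 23 lower and 3 higher (12 and 3 over the list alone; adjusted p = 0.0165, 0.193 estimated), with FASN1 at -2.17 and Fbp1 at -2.30. Heterochromatin factors had 5 of 16 lower and 0 higher (7 and 0 over the list alone; adjusted p = 0.0279, 0.342 estimated, 0.123 without female 3). Polycomb targets had 11 of 65 higher and 0 lower, and 0 over the list alone (adjusted p = 0.00713, 0.988 estimated, 0.1 without female 1, 0.0666 without female 2). Lists that did not pass with all libraries and TMM but passed without a library were the cuticle list with 24 of 110 higher and 29 lower (adjusted p = 0.367; 0.00657 without female 3), neurons (0.2; 0.00419 without female 3), ribosomal proteins (0.0895; 0.0143 with total counts, 0.0127 without wild-type male 2, 0.00214 without female 1, 0.00592 without female 2) and digestive enzymes (0.2; 0.0215 without female 1, 0.0405 without female 2). The trithorax, apoptosis, glia, trachea and yolk lists had medians, means or tests of different sign, and none of them passed. Directions flipped with the arm factors or total counts for the Polycomb and trithorax groups, and with total counts for apoptosis, glycolysis and trachea; a change of scaling moves all genes alike, so such flips of medians near 0 tell nothing about the lists.

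roX-KO males differ from the wild-type females in sex as well as in genotype, and males have a single X. The female libraries were also submitted later, and the labels do not give the stocks. In this comparison none of these can be told apart from the loss of the roX RNAs. Set against females, which also have little roX RNA, roX-KO males had the lower X. This set call held with an estimated correlation (adjusted p = 0.00934), adjusted only among the X, chromosome 4 and pericentromeric sets. Before adjustment its camera p (0.00311) was close to that of the germline list (0.00381). The contrast between the X and that list therefore rests on the adjustment. Many cuticle, tracheal and muscle genes were lower and many germline and cell cycle genes higher, but these lists lost their calls with an estimated correlation (0.114 to 0.509). For germline (-0.015) and muscle (-0.0254) the estimate lay under the preset 0.01, so correlated genes do not explain those losses. Of 11173 genes 1193 were higher in roX-KO males and 1851 lower (27.2% changed), 411 and 989 of them by at least 2-fold, and groups did not overlap in 6110 genes (54.7%, where chance gives 10%). Without female 3 the counts were 3384 and 3566; without roX-KO male 1, 2 or 3 they were 524, 615 or 546 higher and 1014, 1094 or 1030 lower. The share of calls that were higher was 39.2%, and 57.5% with total counts, which moved the median of all genes by 0.21. With arm factors it was 32.2%, and for arm genes 40.9% in place of 48.7%.

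On the X 661 of 1751 genes were lower (37.7%) and 58 higher (3.31%), and on the arms 1183 of 9289 were lower and 1122 higher. X genes were less often higher (odds ratio 0.249, Fisher's exact p = 2.2e-34) and more often lower (4.15, p = 1.01e-122). The X shift was -0.49, so that X expression fell by 28.8% relative to the arms (exact permutation p = 0.1, the smallest possible). Pericentromeric genes shifted by 0.38 (exact permutation p = 0.1), with 45 of 137 higher and 4 lower, and chromosome 4 genes by 0.25 (permutation p = 0.3), or 0.07 without female 3. roX1 was at -2.84; roX2 had too few counts to be tested. As sets, pericentromeric genes (2.78e-06) and chromosome 4 (0.0141) lost their calls with an estimated correlation (0.174 and 0.561).

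Higher in roX-KO males were FDY (log2 fold 6.31), CG9360 (5.84), RpL22-like (5.62), TotA (4.31), gNacalpha (4.05), Kots (3.80), Bace (3.05) and CG15930 (78.9-fold, counting interval 26.7 to 385). Of these, the Y-linked FDY, RpL22-like, gNacalpha and CG15930 were also lower in females against wild-type males, so they go with sex. CG9360, TotA and Bace were also higher in roX-KO males against wild-type males. Lower were CG3588 (at least 12000-fold), CG14419 (6010-fold, interval 1080 to 237000), CG14417 (at least 418-fold), Acbp3 (1910-fold, interval 528 to 15800), CG14147 (-10.14), CG14418 (-9.83), Cpr65Ea (-9.53), Twdlbeta (-8.79), TwdlD (-7.79), sordd2 (-7.65) and nol (-7.43). The gene msl-2 was at 2.26 (adjusted p = 0.00548) and Sxl at -1.09 (0.00483). msl-1 was at 0.78 (0.0227; 0.0855, 0.0784 and 0.0892 without roX-KO male 1, 2 and 3).

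Cuticle proteins had 79 of 107 lower and 2 higher (88 and 3 over the list alone; camera adjusted p = 9.3e-50, 0.196 with an estimated correlation), trachea and epidermis 9 of 16 lower and 0 higher (10 and 0; adjusted p = 4.93e-06, 0.509), and muscle 13 of 20 lower and 0 higher (14 and 0; adjusted p = 0.000309, 0.118). Oxidative phosphorylation had 13 of 62 lower and 1 higher (11 and 1 over the list alone; adjusted p = 0.000381, 0.785 estimated), digestive enzymes 22 of 55 lower and 6 higher (24 and 7; adjusted p = 0.000469, 0.748), and detoxification 13 of 42 lower and 5 higher (15 and 5; adjusted p = 0.016, 0.719). Hemocytes had 4 of 13 lower and 0 higher, also over the list alone, and 2 and 0 with total counts (adjusted p = 0.0134, 0.211 estimated), with PPO1 at -2.25 and PPO2 at -2.39. Germline genes had 11 of 18 higher and 1 lower (13 and 1 over the list alone; adjusted p = 3.79e-07, 0.114 estimated), with vas at 2.99, krimp at 2.60 and piwi at 1.77. DNA replication and cell cycle had 18 of 37 higher and 1 lower (22 and 2; adjusted p = 8.71e-06, 0.118), with CycB3 at 2.19 and CycB at 1.81. Both lists were lower in females against wild-type males. Between the male groups neither rose, with 5 germline genes higher and 5 lower, and 5 cell cycle genes higher and 14 lower. Heat shock genes had 6 of 12 higher and 0 lower, also over the list alone (adjusted p = 0.000469, 0.118 estimated), with Hsp68 at 1.72 and Hsp27 at 1.70. Heterochromatin factors had 8 of 16 higher and 1 lower (9 and 1; adjusted p = 0.0051, 0.221), the Polycomb group 4 of 21 higher and 0 lower, also over the list alone, and 7 and 0 with total counts (adjusted p = 0.00742, 0.719), and the apoptosis list 11 of 25 higher and 4 lower (13 and 5, and 13 and 0 with total counts; adjusted p = 0.024, 0.719).

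None of the 13 functional lists called against females held with an estimated correlation. By fry oxidative phosphorylation (adjusted p = 0.142), digestive enzymes (0.0691) and the Polycomb group (0.0691) lost their calls and the others held. Neurons (adjusted p = 0.0511; 0.043 with arm factors, 0.0319 and 0.0359 without roX-KO male 2 and 3, 0.01 and 0.0254 without female 1 and 2), the trithorax group (0.0685; 0.0467 without roX-KO male 2, 0.0246 without female 1) and ribosomal proteins (0.117; 0.0467 without roX-KO male 2, 0.0062 without female 1, 0.021 without female 2) did not pass with all libraries and TMM but passed under those settings. Polycomb targets, neural stem cells and Malpighian genes had medians, means or tests of different sign. Directions flipped with arm factors for Polycomb targets, larval serum and yolk, and with total counts for the ecdysone, glycolysis and Malpighian lists; none of these passed, and the move of all genes by scaling (0.213 with total counts) is enough to flip a median near 0.

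Many genes changed the same way in roX-KO males and in females against wild-type males. Of 11013 genes tested in both, 716 were higher and 868 lower in both, 1584 together, where independent lists would share 362.8 and 403.2, and 290 went in opposite directions, where independent lists would give 765. Both comparisons use the same wild-type male libraries, so the values for independent lists are not those to be had by chance. With unchanged groups simulated against shared controls, single comparisons gave almost no calls, so they give no chance value for shared calls. The simulated covariance of log2 folds was 0.0128, against 0.256 observed, but a covariance also grows with the size of the changes. The correlation over genes was 0.364 observed and 0.339 simulated (range 0.323 to 0.363), so it was close to what shared controls alone gave. The 3 control libraries are too few to be divided between the comparisons, so the part of the shared calls that comes from them was not measured. Shared calls numbered 3707 without female 3, 739, 886 and 741 without wild-type male 1, 2 and 3, and 963 without female 2.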

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

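The tests on reads outside genes and the test of epidermal tissue share were chosen after the result was seen. Reads counted in no gene made up 46.3% of the reads listed, as a mean of the 9 libraries (45.7 to 47.9%), a signal in lines of the count files that no comparison uses. Over 186 gene pairs in which more than 90% of the exon length of 1 gene lies under a gene on the other strand, the median log2 ratio of its count density to that of the other gene was 0.0957 (95% interval -0.02 to 0.30). This is consistent with a library that does not mark strand, counted on 1 strand. Of the pairs, 60.2% (interval 52.8 to 67.3%) lay within 2-fold of the gene on the other strand. Strand-marked RNA reads from introns or intergenic sequence alone would not bring this about and are argued against. The test does not decide on genomic DNA. Its reads come from both strands, and partners with as few as 100 counts over the 9 libraries were included. No biological explanation was tested. The strand setting of the counting is not given in the sources used here, so folds of genes that overlap another on the other strand stay uncertain.

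In roX-KO males against wild-type males, more arm genes were higher than lower (3212 and 2523), and chromosome 4 and pericentromeric genes stood above the arms. Scaling of libraries in which X genes fell was tested as the cause of the higher arm genes as such. With factors from the arms alone 2794 were still called higher, above the cut set beforehand. These factors moved folds by a median of only -0.0585 and centre the arm genes. With many arm genes changed each way, many must stay higher, so the count does not decide on scaling. It shows only that these genes stood higher relative to the other arm genes. With those factors 49.6% of called arm genes were higher, against 56.0%, which lies in the range set beforehand for scaling as the cause. But the factors centre the arm genes (median log2 fold 0.02), which sets a balance near that value. This limit was not part of the rule set beforehand. Scaling therefore stays open as the cause of the excess of higher over lower. For pericentromeric genes the shift was 0.292 against arm genes matched on expression level and exon length (SD 0.0706) and 0.301 unmatched, which argues against level and length. For chromosome 4 the matched shift was 0.158 (SD 0.0747) and the unmatched 0.237, which leaves part of it open. The loss of the roX RNAs, and differences of strain background, were not separated by these libraries.

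Cuticle protein genes were lower in roX-KO males by a median log2 fold of -2.62. Trachea and epidermis genes fell less, by a difference of medians of 2.2 (interval 1.03 to 2.64), whose lower end barely passed the cut of 1 set after the result was seen. This does not decide on a smaller share of epidermal tissue as the whole cause. The list mixes genes of trachea and epidermis and does not measure the epidermal share alone, and its mean log2 fold (-0.857) lay below its median (-0.418). Along the main axis on which replicates of 1 group differ, such as larval age or handling, loadings of the 109 cuticle genes correlated with their knockout folds at r = -0.219 (interval -0.391 to -0.0319), as did those of all genes (-0.248). The axis was set mostly by female 3 (score 51, against -26.8 and -24.2 in females 1 and 2), which is outside this comparison. The roX-KO males scored 0.102, -1.02 and 0.916. What the axis stands for was not tested. The value for cuticle genes was close to that of all genes, so it shows nothing particular to cuticle genes. The correlation therefore does not decide on larval age or handling as a part of the cause, and the labels give no age within the first instar. A genuine effect of the genotype remains open and untested.

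Other splits of the samples into groups of 3 were counted, 10 for each comparison with the real one included, which is too few for a share under 0.05. For genes, 1 split, the real one, gave as many calls in each direction, and the highest other was 0, against 3505 higher and 3588 lower in roX-KO against wild-type males, 1197 and 1244 in females against males, and 1193 and 1851 in roX-KO males against females. For gene lists with the preset correlation, 5, 10 and 8 splits gave as many calls, with highest others of 15, 16 and 18 against 13, 7 and 13. Each of the other splits mixes the real groups: this keeps part of the real contrast and widens the spread within groups, so few or no gene calls are given in advance, and neither the gene nor the list counts show where the calls come from.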

How the results depend on the processing

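Leaving out wild-type male 2 and female 3 together was chosen after the data were seen; all other settings were planned. Counts of genes, higher and lower, are given in that order; the cause of a move was not tested except where a stricter threshold or fewer libraries sets it. In roX-KO against wild-type males (3505 and 3588), total counts gave 5467 and 2395, all 9 libraries in 1 fit 2040 higher, and the 1.5-fold threshold 842 and 1317. Total counts also turned which count was larger in females against males (1246 and 1107) and in roX-KO males against females (1775 and 1311). In females against males arm factors (1219 and 1217) and all 9 libraries in 1 fit (1755 and 1726) turned it too. In the males, leaving out 1 library gave 3024 to 3675 and 3223 to 3828. In females against males (1197 and 1244) the 1.5-fold threshold gave 330 and 438, adjusted p 0.01 gave 493 and 609, both libraries out 3471 and 3464, and leaving out 1 library 430 to 2927 and 616 to 2924. In roX-KO males against females (1193 and 1851) all 9 libraries gave 1871 higher, the 1.5-fold threshold 342 and 834, adjusted p 0.01 528 and 1032, and leaving out 1 library 524 to 3384 and 1014 to 3566. The X shift between males (-0.473) was -0.431 with no low-count filter, -0.404 with means and -0.389 with deposited FPKM plus 1, and -0.481 to -0.463 with 1 library out. The pericentromeric shift (0.301) was 0.414 with means. The X and chromosome 4 shifts of the other comparisons, and that of chromosome 4 between males, stayed within 1 SD; pericentromeric shifts in the comparisons with females were given no alternative. The autosomal share of genes higher (91.6%) stayed between 91.0 and 92.1%. Shared calls (1584) were 322 at the 1.5-fold threshold and 739 to 3707 with 1 library out. Of 90 list tests 33 were called, 4 with an estimated correlation, 47 by fry and 33 to 37 with 1 library out. Of 399 named results 351 passed, 345 with DESeq2, 342 with arm factors and 299 to 367 with 1 library out, and none reversed. With 1 library out, 4 to 14 named results lost their calls between the male groups, and up to 39 in each comparison with females.

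Replicate numbers did not pair the samples: libraries of the same number correlated at -0.0142, -0.00942 and -0.00681 between the male groups, and 0.396, -0.585 and -0.436 between females and males. With the number as a block, females against males gave 482 and 615, shared calls 761, lists 34 and named results 297. Settings with FPKM exist for the male comparison alone and were not run for the others. Depth left roX2 untested between roX-KO males and females, and the spread of female 3 limited the female comparisons, where simulated changes of 1.5-fold were recovered in 11.9% and 5.97% of cases.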

Other observations

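A block of X genes near w and some pigment genes were looked up after their values were seen. In females against wild-type males, CG14416 (log2 fold 6.06), CG14424 (2.16), CG14421 (2.89) and CG17959 (2.94) were higher beside w, CG14417, CG14418, CG14419 and CG3588, neighbours on the X that start with w and end with CG17959 at 2947580. CG3588 had 65, 59 and 58 counts in wild-type males, 0, 0 and 0 in roX-KO males, and 9931, 10276 and 11493 in females. Against females, roX-KO males had CG14424 at -1.14 and CG17959 at -1.47, while CG14421 did not pass (-0.75, adjusted p = 0.0878). Against wild-type males, roX-KO males had CG14421 at 2.15, CG14424 at 1.03 and CG17959 at 1.48. The cuticle pigment gene y on the X was at -2.96 in roX-KO males against wild-type males, beside v at -4.62.

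Heat shock genes set the wild-type males apart from both other groups: their list median was -2.08 in roX-KO males and -3.23 in females against wild-type males. On the main axis of variation among replicates (75.1% of it) female 3 scored 51 and wild-type male 2 scored 15.4, while females 1 and 2 scored -26.8 and -24.2. Wild-type male 2 and female 3 departed from their groups together (r = 0.667 over genes), and the TMM factor of female 3 was 0.836. The share of counts in mitochondrial genes was 6.77% ± 1.19 (SD, n = 3) in females, against 10.7% ± 1.43 in wild-type males.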
